A study of Mus musculus with 6 samples.

How the data were processed

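Gene expression was measured in neutrophils isolated from mouse bone marrow, 3 samples from germ-free and 3 from control mice, with 1 Illumina bead array for each. Per the labels' protocols, total RNA was extracted with a mirVana kit, cleaned and treated with DNase I, checked on a Bioanalyser and amplified to biotin-labelled cRNA. How the neutrophils were isolated is not given in the sources used here, and neither is a slide or chip position, so a slide effect could not be modelled.

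The authors deposited a table of intensity values with a detection p-value for each of 45281 probes and 6 arrays. Per the submitters' processing notes the tools were GenomeStudio and lumi, with no version given. The deposited intensity values are background-subtracted bead averages that were not normalized across arrays, since 33.8% of them lie below 0 and the medians differ between arrays. The deposited detection p-values move in steps of 1 in 936, the resolution of the negative control probes. The authors also deposited log2 values of the same arrays in 2 identical tables. A recomputation matched them to a quantile normalization of log2 intensities after each array's minimum was subtracted and a small constant added, with a largest gap of 3.21e-04 on the log2 scale. The authors' deposited comparison of the groups holds a signed fold change (a score column here), a t score, and raw and adjusted p-values. The fold change was recomputed as the ratio of mean linear values of germ-free over control arrays, written as a negative reciprocal under 1, and the t score correlated with limma's moderated statistic on those values at r = 1. All 6 arrays have a median of 5.26 in the authors' log2 values.

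The main fit started from the deposited intensities. Background was corrected with the normal-exponential model fitted through the detection p-values, with an offset of 16, and arrays were quantile normalized on the log2 scale (neqc in limma 3.58.1 under R 4.3.3, files read with the data.table package, version 1.17.8). Quantile normalization forces the same distribution on every array and so would hide a global shift. Probes were kept where the detection p was under 0.05 on at least 3 of 6 arrays, 17559 probes, and 5 control probes were left out. A gene with several kept probes, as 3728 genes had, was represented by the probe of highest mean, which gave 12193 genes. Gene symbols came from the deposited tables and were updated through a RefSeq gene table of assembly GRCm38.p6: 27740 probes carried a current symbol, 8037 an older name of 1 gene only, and 9499 kept the symbol of the file. 40 probes carry symbols that a spreadsheet turned into dates. No coordinates are given, since the sources name no build.

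The comparison of germ-free with control arrays was fitted with lmFit and eBayes over all 6 arrays with the group as the only term, two-sided, with Benjamini-Hochberg adjustment at 0.05. Differences are germ-free minus control on the log2 scale with the moderated SE, and values with ± are means and SDs of 3 arrays. A gene undetected on all arrays of a group is given as a bound. The rule for named genes took, in each direction, up to 12 genes of the largest change past the threshold. Where fewer than 5 passed, it took the 10 of smallest unadjusted p, named as not past the threshold. It also took up to 4 members of smallest unadjusted p in each list, and 17 neutrophil genes whatever their p, of which Elane was not measured after the filter. The 2570 genes with placeholder symbols, such as 6430402L23Rik with the smallest p of all, were counted and tested but passed over by the rule.

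The 29 gene lists, 18 of functions and 11 of other cell types that a marrow isolate could hold, were written before the data were examined, as were this rule and the other choices of filter, scaling and model described below, apart from those named as added. They were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the lists, and again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance and does not set the list against other genes. Of the 10 lists past the threshold with the preset correlation, 0 held with an estimated correlation and 0 with fry. The spread within groups was compared by the median log2 ratio of SDs with an exact permutation over the 20 labellings.

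The fit was tested on simulated data: 10 runs of 12193 genes with 200 changed gave a mean of 149.6 calls, 6.7 of them false. A list shifted by 0.5 on the log2 scale was called in 10 of 10 runs, and 1 unshifted list was called over all runs. Those simulated genes varied independently, whereas genes of a list covary in real arrays, so the simulation says nothing of the preset correlation.

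Alternatives changed the background correction, the scaling across arrays, the source of the normalized values, the filter, the variance model, array weights, the probe per gene, a block for the replicate number, the threshold and the list test, and left out each array in turn. A covariate for erythroid genes and counts at an unadjusted p under 0.05 were added after the data were seen. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.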

Results

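Neutrophils, the short-lived granulocytes that make up much of the bone marrow, were isolated from the marrow of germ-free mice, which are raised without microbes, and of control mice whose sample titles read SPF. Total RNA from 6 isolates was hybridised to Illumina mouse bead arrays with 45281 probes, 3 arrays in the germ-free group and 3 in the control group. The labels give C57BL/6 males for all 6 samples. Between 16661 probes (control replicate 2) and 17710 probes (germ-free replicate 2) were detected at a detection p under 0.05, and the mean background-subtracted signal per array ran from 327.7 to 385.0. The labels do not say whether the 3 samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. With 3 arrays in a group, their number limits the precision of every value that follows.

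Granule and calcium-binding protein genes of neutrophils were measured near the top of the intensity range in both groups, where differences are compressed. Lcn2, an iron-siderophore-binding protein of the specific granules, had a normalized log2 intensity of 16.01 ± 0.02 (SD, n = 3) in germ-free and 16.03 ± 0.01 (SD, n = 3) in control arrays. Ltf, which encodes lactoferrin, stood at 15.96 ± 0.02 and 15.97 ± 0.02, S100a8 at 15.84 ± 0.06 and 15.82 ± 0.07, and Mpo, the myeloperoxidase of the azurophil granules, at 15.70 ± 0.09 and 15.72 ± 0.17 (SD, n = 3 each). Probes for genes of other cells were as bright, such as Prg2, an eosinophil granule protein, at 15.99 in germ-free and 15.73 in control arrays. Of the 17 neutrophil genes chosen in advance, 16 were measured, and their differences between germ-free and control ran from -0.09 (Camp) to 0.81 (Il1b) on the log2 scale. Cxcr4, the chemokine receptor that holds neutrophils in the marrow, had the smallest p of them (0.0278 before adjustment), with 11.55 ± 0.40 in germ-free against 10.95 ± 0.19 in control arrays.

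**Figure D1:**
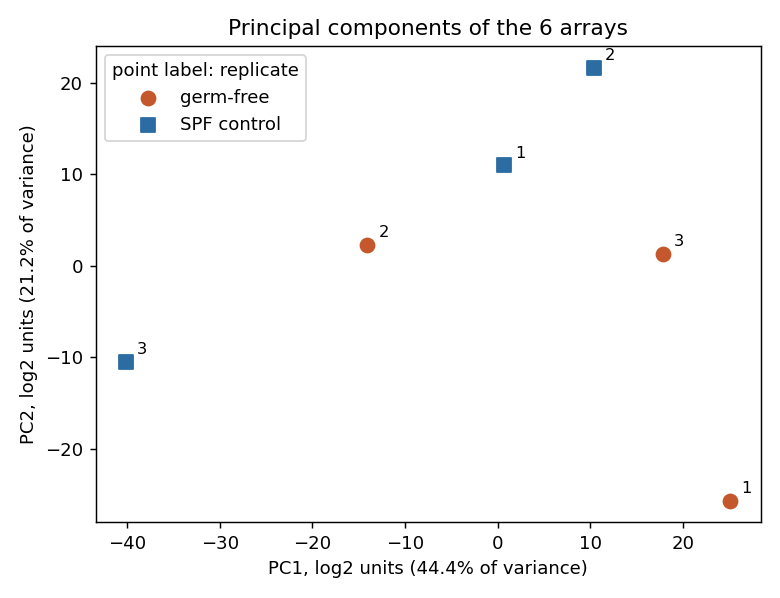
Principal components 1 and 2 (log2 units) of the normalized values of 12193 genes on the 6 arrays, with germ-free arrays as circles and control arrays as squares, each labelled by its replicate number. The first component holds 44.4% of the variance and runs from control replicate 3 at -40.1 to germ-free replicate 1 at 25.1, and arrays of both groups lie on each side of 0.

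The first question, implied by the labels, was which genes differ in neutrophils from mice without microbes. Among the 10 genes of smallest p that were higher in germ-free arrays, Galm, a galactose mutarotase, was 2.96-fold higher (log2 difference 1.56, SE 0.28), with 8.63 ± 0.43 in germ-free and 7.07 ± 0.44 in control arrays. Klrg1, an inhibitory lectin-like receptor best known from lymphocytes, was higher by 1.00 (SE 0.20) with 1 of 3 control arrays detected, Tspan17, a tetraspanin, by 0.87 (SE 0.18), Lgals4, which encodes galectin-4, by 0.84 (SE 0.18), Pdk1, a pyruvate dehydrogenase kinase, by 0.67 (SE 0.15) and Egfl8 by 0.57 (SE 0.13), all on the log2 scale. Chst1, Ttc30b, Coq3 and Tcrd-V1 were detected on 3 germ-free arrays and on 0 control arrays, so they have only a bound: at least 1.36-fold higher for Chst1, 1.63-fold for Ttc30b, 1.30-fold for Coq3 and 1.23-fold for Tcrd-V1. Each bound sets the mean of the brighter group against, per array, the higher of the lowest detected signal and the dim probe's own value. The second probe of Lgals4 gave 0.69 and that of Egfl8 0.67, while the dimmer probe of Tspan17 gave 0.37.

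Among the 10 genes of smallest p in the other direction, an immunoglobulin heavy chain variable probe stood out by size. Igh-VJ558, named for the largest variable gene family of the heavy chain, was 9.22-fold lower in germ-free arrays, at 10.06 ± 1.02 against 13.27 ± 0.82 in control arrays (log2 difference -3.20, SE 0.55). Its second probe gave -3.19 (SE 0.48). The members of this family are nearly identical, so which of them the probe measured is uncertain. Bckdhb, a subunit of the branched-chain ketoacid dehydrogenase, was detected on 3 control arrays and on 0 germ-free arrays, at least 2.20-fold lower in germ-free, and Pdgfa, a growth factor gene, was likewise at least 1.30-fold lower. Itgb3bp, a centromere component, was 2.92-fold lower and detected on 2 of 3 germ-free arrays, and Igsf9 was 2.13-fold lower. Rdh12, a retinol dehydrogenase, was lower by 1.71-fold, with -0.76 (SE 0.21) on its second probe, and Fam20b, a glycosaminoglycan xylosylkinase, by 1.71-fold. Cited4 (1.92-fold, detected on 2 of 3 germ-free arrays), Foxn2 (1.79-fold, 1 of 3) and Slc25a32 (1.65-fold, 1 of 3) complete the 10.

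**Figure D2:**
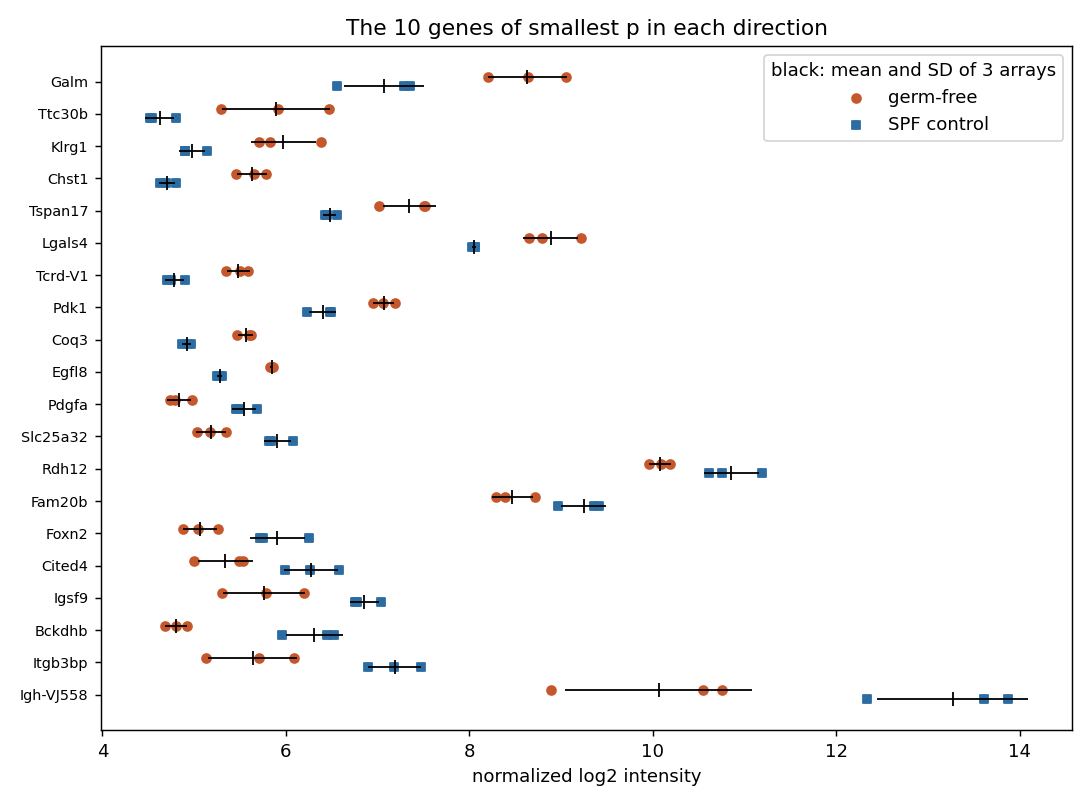
Normalized log2 intensity on the x axis of the 10 genes of smallest p in each direction, with 1 point per array (germ-free circles, control squares) and black marks for the mean and SD of 3 arrays. Igh-VJ558 had a mean of 10.06 in germ-free against 13.27 in control arrays, and the groups do not overlap for any of the 20 genes, which were picked for their small p.

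None of these 20 genes passed the threshold. With the replicate block, though no label says that the replicate numbers pair the arrays, Igh-VJ558 did (adjusted p = 0.0194). By limma with Benjamini-Hochberg adjustment, 0 of 12193 genes were higher and 0 were lower at an adjusted p under 0.05, and the smallest adjusted p was 0.152. At an unadjusted p under 0.05, 257 genes were higher and 202 lower in germ-free arrays, 459 in all, where 609.7 would be expected by chance. The 2 groups did not overlap for 8.19% of the genes, against 10% by chance. In simulated arrays with the same gene means and spreads, 200 of 12193 genes were changed and genes varied independently. The same fit recovered 54.3% of genes changed 2-fold and 88.6% of genes changed 4-fold there. The adjusted threshold depends on how many genes change, so these shares do not carry over to arrays in which few genes changed or genes covary. Leaving out an array moved the count of genes at an unadjusted p under 0.05 by more than 1.5 times: 684 were higher and 502 lower without germ-free replicate 2, and 157 were higher without germ-free replicate 1 and also without germ-free replicate 3. Without germ-free replicate 1, Rnase12 passed the adjusted threshold (adjusted p = 0.0181), without germ-free replicate 3 Casp9 did (adjusted p = 0.00531), and without control replicate 3 Gin1 did (adjusted p = 0.0398). Each of these 3 probes sat at separate low and high levels, and the array left out was the 1 whose level differed from the rest of its group. The other 2 Casp9 probes gave 0.36 (SE 0.29) and 0.15 (SE 0.22). Rnase12 and Gin1 were named only after their values were seen.

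The authors' deposited table gives the same picture over all 45281 probes. It holds 0 probes at an adjusted p under 0.05, with a smallest adjusted p of 0.114, and 2234 probes, 4.93% of all, at a raw p under 0.05. In the authors' deposited table the Igh-VJ558 probe has a fold change of -8.73 (the minus sign marks lower in germ-free) with an adjusted p of 0.805, and Bckdhb has -2.51 with an adjusted p of 0.529.

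The second question was whether genes of a known function or cell type shifted together. Genes of eosinophils and of basophils and mast cells, other granulocytes of the marrow, were higher in germ-free arrays. All 6 measured eosinophil genes were higher, with a median log2 difference of 0.78 (adjusted p = 3.03e-06 by camera with a preset correlation), 4 of them at an unadjusted p under 0.05, 3 at an adjusted p under 0.05 adjusted over the list alone and 0 over all genes tested. With an estimated correlation the eosinophil list did not pass (adjusted p = 0.644). Ear6, an eosinophil ribonuclease, was at 14.45 ± 0.34 in germ-free against 13.46 ± 0.51 in control arrays, Epx, the eosinophil peroxidase, at 11.34 ± 0.35 against 10.44 ± 0.51, and Prg3, an eosinophil granule protein, at 12.07 ± 0.30 against 11.28 ± 0.46 (SD, n = 3 each). Ear2 differed by 0.38 (SE 0.15) on its brightest probe, near the top of the range. Its dimmer probes gave 0.58 (SE 0.22), 0.60 (SE 0.23) and 1.36 (SE 0.42). The eosinophil ribonucleases are near-identical copies, so the probes of Ear2 and Ear6 may share transcripts. All 10 basophil and mast cell genes were higher too, with a median of 0.89 (adjusted p = 3.03e-06, and 0.644 with an estimated correlation) and 3 at an unadjusted p under 0.05, 0 of them adjusted over the list alone. Il4, the cytokine that basophils secrete, was higher by 0.98 (SE 0.29), Gata2, a transcription factor of basophils and mast cells, by 0.80 (SE 0.27), Cd200r3 by 1.03 (SE 0.37) and Cpa3, a mast cell carboxypeptidase, by 1.16 (SE 0.54). For the eosinophil list control replicate 3 stood apart at a mean deviation of -0.82, against 0.00 and -0.20 in the other control arrays, and without it the median was 0.43 (adjusted p = 1.57e-04). Control replicate 3 had a mean deviation of 0.25 for the basophil list, above the 0.23 of germ-free replicate 3, and the other control arrays stood at -0.49 and -0.96. Without control replicate 2, the lowest of them, the basophil and mast cell median was 0.57 (adjusted p = 7.19e-04).

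B lineage and plasma cell genes moved the other way. All 13 measured B lineage genes were lower in germ-free arrays, with a median of -0.45 (adjusted p = 0.00205, and 0.644 with an estimated correlation), 0 of them at an unadjusted p under 0.05. Blk, a tyrosine kinase of B cells, was at 8.89 ± 0.60 against 9.55 ± 0.42, Cd79b, a chain of the B cell receptor, at 11.74 ± 0.63 against 12.43 ± 0.53, Rag1 at 6.43 ± 0.63 against 7.06 ± 0.51 and Cd22 at 7.42 ± 0.50 against 7.87 ± 0.36 (SD, n = 3 each). The 3 measured plasma cell genes were lower as well, with a median of -0.40 (adjusted p = 0.0273, and 0.644 with an estimated correlation): Mzb1 by -0.92 (SE 0.40), Irf4 by -0.40 (SE 0.30) and Xbp1, a factor of antibody secretion, by -0.31 (SE 0.21). The B lineage shift rested on single arrays: the mean deviation was 0.92 in control replicate 3 and -0.84 in germ-free replicate 1, against values between -0.17 and 0.24 in the other 4 arrays. Without control replicate 3 the B lineage median was -0.07 (adjusted p = 0.653) and the plasma cell median -0.19 (adjusted p = 0.248), and without germ-free replicate 1 they were -0.08 (adjusted p = 0.322) and -0.31 (adjusted p = 0.169). With array weights the B lineage list (-0.21, adjusted p = 0.115) and the plasma cell list (-0.35, adjusted p = 0.0849) did not pass.

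Of the 11 measured genes of T and NK cells, 8 were higher and 3 lower in germ-free arrays, with a median of 0.39 (adjusted p = 0.0273, and 0.644 with an estimated correlation) and 0 at an unadjusted p under 0.05. Klrd1, a receptor of NK cells, differed by 0.50 (SE 0.25), Cd3g by 0.63 (SE 0.39), Lck by 0.39 (SE 0.25) and Ccl5 by 0.33 (SE 0.19). Control replicate 3 stood at -0.69 in the mean of this list, and without it the median was 0.07 (adjusted p = 0.850). The median without germ-free replicate 3 was 0.20 (adjusted p = 0.163), and without germ-free replicate 2 it was 0.43 (adjusted p = 0.0588). With array weights the T and NK cell list did not pass (0.27, adjusted p = 0.134).

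Receptors for adhesion, chemotaxis and exit from the marrow were higher in germ-free arrays as a group. Of 17 measured members 12 were higher and 5 lower, with a median of 0.34 (adjusted p = 0.00446, and 0.644 with an estimated correlation), 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Cxcr4 was higher by 0.60 (SE 0.22), C5ar1, the receptor of complement C5a, by 0.54 (SE 0.23) and Cd44, a hyaluronan receptor, by 0.42 (SE 0.17). The 2 dimmest of the 5 Cd44 probes gave -0.02 and -0.06. Inflammatory cytokine genes and other targets of NF-kB were also higher, 20 of 22 measured, with a median of 0.22 (adjusted p = 0.0344, and 0.644 with an estimated correlation). Ccl4 and Ccl3, chemokines that attract macrophages, were at 11.49 ± 0.62 against 10.67 ± 0.45 and at 11.54 ± 0.79 against 10.62 ± 0.51, while Relb differed by 0.30 (SE 0.18) and Sod2 by -0.24 (SE 0.14). Il1b, at 12.23 ± 0.77 against 11.43 ± 1.65, and Cxcl2, at 9.19 ± 1.28 against 8.89 ± 2.06, varied more within the control group than between groups. Control replicate 3 had the lowest mean of both lists, -0.32 and -0.66. Without it the receptor median was 0.22 (adjusted p = 0.0927) and the NF-kB median 0.04 (adjusted p = 0.959). The NF-kB median was 0.09 (adjusted p = 0.473) without germ-free replicate 1 and 0.15 (adjusted p = 0.163) without germ-free replicate 3. The NF-kB target and inflammatory cytokine list also did not pass with no filter on dim probes (median 0.11, adjusted p = 0.134) or with array weights (0.21, adjusted p = 0.134). Immediate early and heat shock genes, listed as a sign of handling, were likewise lowest on control replicate 3 (mean deviation -0.54). Handling was not tested as a cause.

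Genes of oxidative phosphorylation, cell division and sterol synthesis were lower in germ-free arrays by small amounts. Of 21 measured genes of the first group, the mitochondrial chain that makes ATP, 20 were lower, with a median of -0.17 (adjusted p = 0.00141, and 0.644 with an estimated correlation). Cox5a differed by -0.23 (SE 0.14), Ndufb5 by -0.29 (SE 0.18), Sdhb by -0.24 (SE 0.16) and Cox4i1 by -0.25 (SE 0.18). Of 26 measured genes of the cell cycle and DNA replication, 23 were lower, with a median of -0.16 (adjusted p = 0.00205, and 0.644 with an estimated correlation), among them Nusap1 at -0.44 (SE 0.19), Stmn1 at -0.50 (SE 0.23) and Cdc20, an activator of the anaphase-promoting complex, at -0.28 (SE 0.15). Of 14 measured sterol biosynthesis genes, 11 were lower, with a median of -0.19 (adjusted p = 0.00475, and 0.644 with an estimated correlation): Insig1 at -0.38 (SE 0.18), Fdps at -0.35 (SE 0.17) and Msmo1 at -0.29 (SE 0.16). Dimmer probes gave 0.07 for Fdps, -0.07 and -0.45 for Insig1, and -0.03 to -0.25 for Cdc20. In these 3 lists 0 genes had an adjusted p under 0.05 adjusted over the list alone, and 1 had an unadjusted p under 0.05. Without control replicate 3 the medians were -0.09 (adjusted p = 0.0635), -0.06 (adjusted p = 0.331) and -0.12 (adjusted p = 0.0503), in the same order. The sterol median was -0.13 (adjusted p = 0.0549) without germ-free replicate 1 and -0.22 (adjusted p = 0.0512) without germ-free replicate 2. The cell cycle list had its highest mean deviation in control replicate 3 (0.26) and its lowest in germ-free replicate 1 (-0.17). The B lineage list did too (0.92 and -0.84), and a share of B lineage cells was not tested as a cause.

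**Figure D3:**
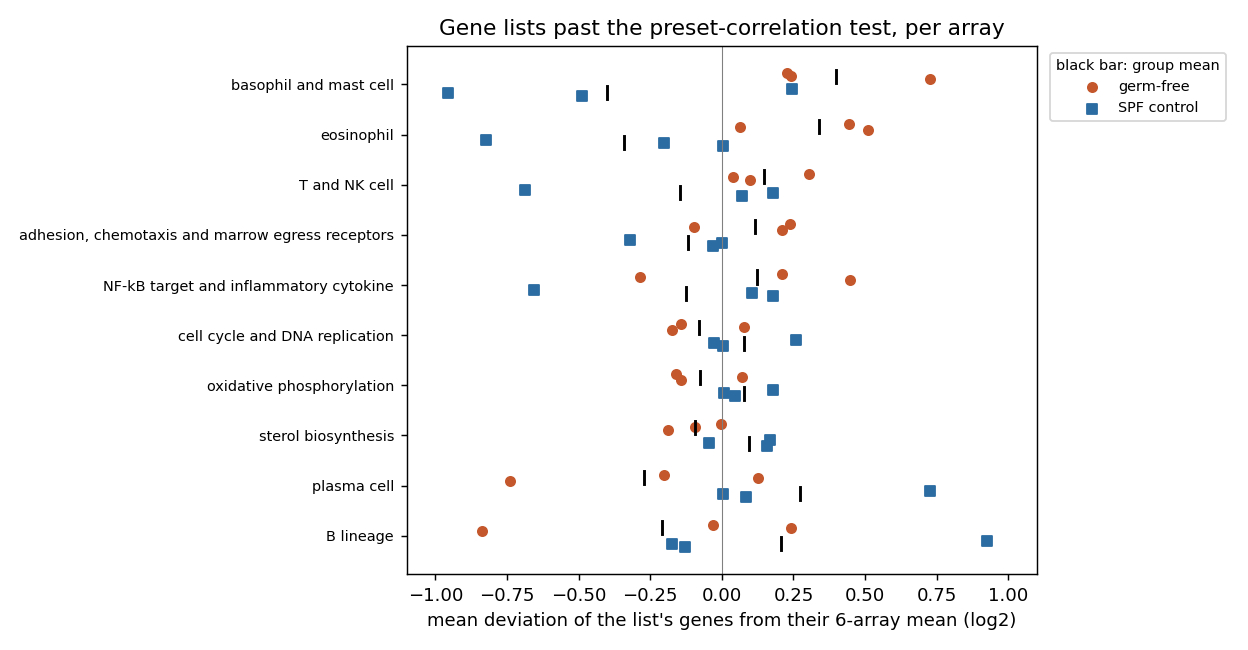
Mean deviation (log2) of each list's genes from their mean over the 6 arrays, for the 10 lists past camera's test with a preset correlation, with 1 point per array (germ-free circles, control squares) and black bars for group means. For the B lineage, control replicate 3 lies at 0.92 and germ-free replicate 1 at -0.84, and for T and NK cells control replicate 3 lies at -0.69.

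The remaining 19 of the 29 lists did not pass. Erythroid genes varied most between arrays. Control replicate 2 stood at 1.62 in the mean of this list and control replicate 3 at -0.94, against values from -0.35 to -0.03 in the other 4, and the list had a median difference of -0.25 (adjusted p = 0.121), and -0.36 (adjusted p = 0.0434) without control replicate 1. Without control replicate 2 the erythroid median was 0.07 (adjusted p = 0.194). The erythroid list also passed with the replicate block (adjusted p = 0.0338). These calls used camera's preset correlation, and with an estimated correlation the main fit gave this list an adjusted p of 0.691. Hbb-b1, a haemoglobin chain, was at 15.57 ± 0.72 in control and 15.98 ± 0.03 in germ-free arrays on its brightest probe, near the top of the range. Its dimmer probes went both ways, from 0.39 (SE 0.29) to -1.07 (SE 1.20) on the dimmest. Of the 25 measured genes of Toll-like and NOD-like receptor signalling, the sensors of microbial products, 14 were higher and 11 lower, with a median of 0.03 (adjusted p = 0.205). Tlr8 differed by 0.64 (SE 0.22), Tlr6 by 0.55 (SE 0.24) and Pycard by -0.47 (SE 0.17), while second probes gave 0.05 (SE 0.24) for Tlr6 and 0.01 (SE 0.14) for Pycard. Nlrp3 was at least 1.16-fold higher with 0 control arrays detected, and Nod1 was at 10.10 ± 0.28 in germ-free against 10.07 ± 0.18 in control arrays (SD, n = 3 each). Tlr4 differed by -0.05 (SE 0.23), Tlr2 by 0.28 (SE 0.28) and Myd88, the adaptor of these receptors, by 0.14 (SE 0.16), with -1.07 (SE 0.72) on its dimmer second probe.

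With all 6 arrays, the lists of interferon responses and of granules did not pass. The type I interferon list had 9 genes higher and 14 lower (median -0.06, adjusted p = 0.902), although Ifit3 was at 7.23 ± 0.27 in germ-free against 6.30 ± 0.58 in control arrays. The list of interferon gamma response and MHC class I had a median of -0.06 (adjusted p = 0.778). Azurophil granule genes had a median of -0.10 (adjusted p = 0.536), gelatinase granule and late neutrophil genes 0.18 (adjusted p = 0.0726) and NADPH oxidase genes 0.06 (adjusted p = 0.371). For the specific granule list (adjusted p = 0.902) the median was -0.00 and the mean 0.01, and Cd177, a neutrophil surface protein, was at 14.72 ± 0.33 against 14.03 ± 0.36. Without control replicate 3 the azurophil list passed at a median of -0.26 (adjusted p = 0.0364), the erythroid list at -1.17 (adjusted p = 2.00e-05) and the immediate early and heat shock list at -0.20 (adjusted p = 0.00274), which stood at 0.01 with all arrays (adjusted p = 0.763). The gelatinase granule and late neutrophil list lay near the threshold. With all 6 arrays it passed with no background correction (adjusted p = 0.0479), median scaling (0.0467), the stricter detection filter (0.0498), the replicate block (0.0462) and the erythroid covariate (0.0353). All of these used camera's preset correlation, and with an estimated correlation the main fit gave it an adjusted p of 0.644. It passed without germ-free replicate 2 at 0.32 (adjusted p = 0.0104) and without control replicate 2 at 0.29 (adjusted p = 0.0336).

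Among the other lists, cytosolic ribosomal protein genes had a median of -0.08 (adjusted p = 0.0677), with Rps2 at -0.40 (SE 0.14) and -0.10 on its second probe, glycolysis genes 0.12 (adjusted p = 0.0798), with Slc2a1, a glucose transporter, at 0.41 (SE 0.23), and circadian clock genes 0.12 (adjusted p = 0.0969), with Cry2 at 0.53 (SE 0.21). Without control replicate 2 the ribosomal list passed at -0.15 (adjusted p = 0.0101) and the glycolysis list at 0.16 (adjusted p = 0.0265), and without germ-free replicate 2 the ribosomal list passed at -0.14 (adjusted p = 0.00511). With all 6 arrays the cytosolic ribosomal protein list passed with no background correction (adjusted p = 0.0394), the mean of all probes (0.0410) and the erythroid covariate (0.0247), and glycolysis with that covariate (0.0424). These calls used camera's preset correlation. With an estimated correlation the main fit gave adjusted p-values of 0.691 for the ribosomal and 0.644 for the glycolysis list. Apoptosis and survival genes had a median of 0.02 and a mean of -0.02 (adjusted p = 0.297). In that list Bcl2, which protects from apoptosis, differed by 0.57 (SE 0.16) with 0.10 on its second probe, and the leading Casp9 probe fell into separate levels that did not follow the groups, 5.23, 4.79 and 9.10 on the germ-free arrays and 8.66 to 8.87 on the control arrays. The list of aryl hydrocarbon receptor targets and microbial metabolite receptors had a median of 0.01 with a test direction towards lower (adjusted p = 0.652), and Hcar2, the niacin receptor, was at 9.47 ± 0.42 in germ-free against 8.47 ± 1.69 in control arrays. Megakaryocyte and platelet genes had a median of 0.17 (adjusted p = 0.476), and 3 of 4 measured, Gp5 and Itga2b among them, had an adjusted p under 0.05 adjusted over the list alone. Itga2b, a platelet integrin, was higher by 0.87 (SE 0.27), and Gp5 was at least 1.15-fold lower with 0 germ-free arrays detected. Stem and progenitor cell genes had a median of 0.01 (adjusted p = 0.509), with 1 gene, Meis1 at 0.59 (SE 0.14), under 0.05 adjusted over the list alone. Dendritic cell genes had a median of -0.38 (adjusted p = 0.121), and -0.66 (adjusted p = 0.00848) without germ-free replicate 2. Monocyte and macrophage genes had 0.05 (adjusted p = 0.763), with Adgre1 at 0.49 (SE 0.23), and stroma and endothelium genes -0.01 (adjusted p = 0.902).

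The series title speaks of variability, so the spread within each group was compared. The median SD over genes was 0.22 in germ-free and 0.20 in control arrays, and 6605 of 12193 genes had the larger SD in the germ-free group. The median log2 ratio of the germ-free over the control SD was 0.11 (exact permutation over 20 labellings of the 6 arrays, two-sided p = 0.70), and 0.1 is the smallest p this design allows. Between germ-free arrays the correlations across genes ran from 0.976 to 0.984 and between control arrays from 0.969 to 0.988, while arrays of different groups correlated at 0.962 to 0.989. Genes are not independent replicates, so these correlations carry no p.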

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

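The counts at an unadjusted p under 0.05 and the erythroid covariate were chosen after the data were seen. The count of genes at an adjusted p under 0.05 was 0 in both directions under every normalization, filter, variance model and probe rule tried, and 0 to 1 in each direction when an array was left out. At an unadjusted p under 0.01 with a 1.5-fold change, 46 genes were higher and 31 lower, by construction of the looser threshold. The counts at an unadjusted p under 0.05 were 257 higher and 202 lower genes, of 12193 tested. With no filter they became 632 and 634, of 28903 tested, and with the stricter filter 152 and 125, of 8861 tested. With array weights they became 473 and 410. The causes of these changes, beyond the number of genes tested, were not tested. Over left-out arrays the counts ran from 157 to 684 and from 135 to 502. No label says that the replicate numbers pair the arrays, and the values gave no sign of a pairing. Deviations of arrays with the same number correlated at 0.08, -0.35 and -0.26, and those with different numbers at -0.19 to 0.39. Deviations within a group sum to 0, so these correlations cannot settle the point. With the replicate block 188 genes were higher and 137 lower at an unadjusted p under 0.05, 0 higher and 1 lower (Igh-VJ558) past the adjusted threshold, and 12 lists passed. The 10 lists became 0 with an estimated correlation, 0 with fry, 6 with array weights (the cause was not tested), and 5 to 13 over left-out arrays, 5 of them without control replicate 3, of which 2, eosinophil and basophil and mast cell, were among the 10. The test direction turned without control replicate 3 for the NF-kB target and inflammatory cytokine list (median 0.0409 there, up to 0.39 over left-out arrays) and for the immediate early and heat shock list (-0.20 to 0.21), and the cause was not tested. Of 2469 values of 147 named genes under the alternatives, 50 changed sign without being called, and 0 of those belonged to the 20 genes of smallest p. Of 520 values of the 29 lists, 29 changed sign, in 12 lists. The ratio of SDs kept its sign under the 6 alternatives that could change it, though with a p that cannot pass; the variance prior leaves it as it is by construction. The slide block was not run. Signals near the detection limit bound what could be seen for dim genes.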

Other observations

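All tests weighed in this part other than the splits of the arrays were chosen after the results were seen. Most immunoglobulin probes, grouped by name after their values were seen, were lower in germ-free arrays. Of 41 kept probes of variable and constant genes, 36 were lower and 5 higher, 14 and 1 of them at an unadjusted p under 0.05. The median log2 difference was -0.73, and -0.35 without control replicate 3. Ighg, a constant gene of the gamma isotype, was at 7.87 ± 1.14 in germ-free against 10.26 ± 1.08 in control arrays on 1 probe and at 6.21 ± 0.76 against 6.65 ± 0.51 on another, and Ighg1 at 5.16 ± 0.18 against 5.93 ± 0.36 (SD, n = 3 each). Variable genes are near-identical copies, so single members are uncertain.

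Transcripts of the sex chromosomes did not follow the label. The labels give male for all 6 samples, yet all 4 Xist probes were detected on all 6 arrays, at log2 values from 6.11 to 10.24. Of 12 probes for the Y-linked genes Ddx3y, Eif2s3y, Kdm5d, Usp9y and Uty, 10 were undetected on all 6 arrays, and 2, for Ddx3y (6.69 to 7.68) and Uty (5.38 to 6.24), were detected on all.

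The real grouping did not stand apart from other splits. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 459 genes at an unadjusted p under 0.05, and 6 of the 10 splits gave as many. The highest other split, which sets germ-free replicates 1 and 3 with control replicate 2 against the rest, gave 1982. It was picked for its count, and genes covary, so the count cannot tell a structure of the samples from chance. The same split orders 2 of the 4 Xist probes and both detected Y-linked probes, the latter in opposite directions. Since 1982 of 12193 genes reached that threshold, single probes that follow the split carry little weight. The first Xist probe was at 7.89, 8.02 and 8.13 on germ-free replicates 1 and 3 and control replicate 2, against 9.34 to 9.86 on the others, Ddx3y was at 6.69 to 7.08 against 7.38 to 7.68, and Uty at 5.74 to 6.24 against 5.38 to 5.59. At an adjusted p under 0.05 all 10 splits gave 0 genes, the highest other included. For lists, the real split gave 10, the highest other 14, and 3 of the 10 splits gave as many.

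The eosinophil and the basophil and mast cell lists were higher in germ-free arrays, and 0 of the planned lists held with an estimated correlation. A smaller neutrophil share would raise the markers of every other cell type alike. The mean of these 2 lists moved apart from the B lineage mean by 1.17 (SE 0.53) on the log2 scale. The B lineage shift itself rested on control replicate 3 and germ-free replicate 1, so this gap cannot set a smaller neutrophil share aside. Without control replicate 3 the medians of the 2 lists were 0.43 and 1.21. The larger adjusted p was then 1.57e-04 by camera with a preset correlation. For the basophil and mast cell list that array was the highest control, so leaving it out could only raise the mean difference. The eosinophil median fell from 0.78 to 0.43 but kept its sign, so that array carried part of it. The most abundant of these genes were already near the top of the range, Prg2 at 15.99 in germ-free and 15.73 in control arrays, and Kit also stands in the stem and progenitor list. A larger share of these granulocytes, or more of their transcripts per cell, in germ-free marrow isolates may be at work and was not tested against the germ-free state itself.

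Most immunoglobulin probes were lower in germ-free arrays. A smaller share of B lineage cells in those isolates stays open for the family, whose mean difference lay -0.34 (SE 0.22) from that of the B lineage. For Igh-VJ558 the difference lay below that of the lowest marker, Cd79b, by -2.51 (SE 0.48). That gene was picked for its small p and large drop in these same arrays. Its gap therefore cannot decide whether a changed share of cells is enough. Control replicate 3 alone cannot be told apart from a group effect, since without it the family's median was -0.35, which is neither near 0 nor near the full difference. Fewer antibody-secreting cells in germ-free mice were not tested as a cause, and the plasma cell list, at a median of -0.40 with all arrays, did not pass without control replicate 3 (-0.19, adjusted p = 0.248) or without germ-free replicate 1 (-0.31, adjusted p = 0.169). The sources used here name no sort that would remove B cells.

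Some probes sat at separate low and high levels across the arrays without following the groups. Of 107 such probes, with a gap of at least 1.5 on the log2 scale, 0 split the arrays by group, 38 set control replicate 2 apart, 39 control replicate 3, and 30 split them otherwise. H2-Eb1, an MHC class II chain, was at 6.00 in germ-free replicate 1 against a mean of 10.48 in the others, a difference of -4.48, and fewer antigen-presenting cells there do not account for all of it, since the mean difference of the brightest H2-Ab1 and Cd74 probes was -0.58, and all 6 probes of these genes lay between -0.20 and -1.70, the lowest on a dimmer H2-Ab1 probe (SD of the other arrays 0.73). Inherited sequence differences between mice, despite the shared strain label, may explain part of them: genes with the same split lay beside each other in 1 pair, Myd88 (its second probe) and Vill, against 0.0259 pairs by chance (permutation p = 0.0258), but that pair prompted the test, which keeps it open. H2-Ea, which C57BL/6 mice do not express, reached 8.55 in germ-free replicate 2 and 7.83 in control replicate 1. Other H2 probes were also lowest in germ-free replicate 1: an H2-T23 probe at 4.82, an H2-K1 probe at 6.65, and H2-Q6 at 6.59 and 6.81. The other H2-K1 probe, at 8.96, was not, nor were H2-Ea and some H2-Ab1 probes. A difference of the H2 region between mice was not tested.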
